A study of Rattus norvegicus with 4 samples.

How the data were processed

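Poly(A) RNA of primary hippocampal neuron cultures from rat embryos was measured in 4 cultures, 2 treated with Gld2 shRNA and 2 treated with scrambled shRNA. Per the labels' protocols, the RNA was thermally eluted from poly(U) Sepharose, amplified and labelled with the Ambion WT Expression and Affymetrix WT Terminal Labeling kits, and biotin was the label. The deposited values are on the log2 scale and were made with RMA and the affy package, per the submitters' processing notes. RMA corrects background, brings arrays to a common distribution and summarises the probes of a probe set, but its settings, probe set definition and versions are not given in the sources used here. The log2 scale was read from the deposited values, which run from 3.23 to 14.3. The medians of the 4 arrays were 8.41 to 8.48, and the SD over genes was 1.95 and 1.89 in the Gld2 shRNA cultures and 1.96 and 1.95 in the scrambled shRNA cultures. No further normalization was applied. No detection calls, scan dates or batches were among the sources used here, so signal over background and batch effects were not tested, and the number of arrays limits the precision.

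The table held 28826 probe sets. The platform annotation gave 1 gene symbol for 15209 of them, several for 306 and none for 13311, and 15178 gene identifiers matched the RefSeq gene table of assembly GRCr8, with 0 symbols changed by the match. Probe sets with 1 symbol gave 14497 genes, and for 494 genes with more than 1 probe set the one with the highest mean over the 4 arrays was used. Of the 594 genes called, 19 had more than 1 probe set, 2 of these had a probe set with the opposite sign, and 0 of those opposite probe sets had an unadjusted p under 0.05. The build behind the array annotation is not given in the sources used here, so no coordinates are printed.

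The groups were compared with the lmFit and eBayes functions of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 14497 genes and a threshold of 0.05. The groups left 2 residual degrees of freedom, to which the moderation across genes added 3.96. A second, descriptive count took genes at an unadjusted p under 0.05 and at least 1.5-fold. Confidence intervals of 95% came from the moderated standard errors. Differences are Gld2 shRNA minus scrambled shRNA on the log2 scale.

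Of 26 gene lists and cell type marker sets, each was compared with all other genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the residuals called 0 lists, with 2 at an unadjusted p under 0.05, and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, called 2 lists, the interferon and sterol lists. With 2 residual degrees of freedom, camera with an estimated correlation has little power. Even the interferon list reached only an unadjusted p of 0.0341 by it, so a call lost there is not evidence that a list did not shift. Conversely, the estimates ran from -0.0462 (dividing cell markers) to 0.471 (excitatory neuron markers), with 0.323 for the interferon and 0.406 for the channel list. The preset 0.01 lies far below the higher estimates, so camera p-values of those lists may be much too small. No list had a median whose sign opposed its test. Members were counted past the threshold over all genes and adjusted over the list alone.

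The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The named genes were Tent2, Grin2a, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out unnamed gene models and receptor families of smell, and up to 4 members of each list with the smallest p. Further members are named where a count of 5 or fewer is given or to show the range of a list, and these were chosen after their values were seen. The alternatives were a prior variance that follows the level, filters on dim genes at the median and the 25th percentile, cyclic loess, median centring, the mean of a gene's probe sets, all 28826 probe sets, the final digits of the sample titles as a replicate block, leaving out each culture, a linear model without moderation, other thresholds, and the other list tests. Leaving out a culture left 1 culture in its group, which was assumed to vary like the other group. Removal of a trend with gene length, alone or after cyclic loess, was added after the data were seen. Gene length was the genomic span in the RefSeq table of GRCr8, missing for 25 genes, and the trend of each array was a lowess curve with a span of 0.3.

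The test was tried on simulated data for this comparison, with 14497 genes and 50 genes changed at each size. It recovered 2% of genes changed 1.25-fold, 74% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 8 false calls, 5.52% of all calls. The simulated variances came from the distribution that limma fitted, alike in both groups, with independent genes and no trend with level or length. A false share near the threshold was thus built in and may not hold for the arrays. Of 26 simulated lists, camera called the 1 list shifted by 0.2 and 0 of the others, but the simulated genes were independent, unlike those of the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.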

Results

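The series profiled poly(A) RNA of primary hippocampal neuron cultures from rat embryos with whole-transcript Affymetrix arrays. Gld2 (gene symbol Tent2, formerly Papd4) is a cytoplasmic poly(A) polymerase that lengthens the tails of selected mRNAs in the cytoplasm. The title and design text state the purpose as the profiling of poly(A) RNA after knockdown of Gld2. In each group 2 cultures were studied, treated with an shRNA against Gld2 or with a scrambled control shRNA, on 4 arrays in all. Before labelling, the RNA had been bound to poly(U) Sepharose and released by heat, so each value reflects the amount of a transcript in the RNA recovered that way. The labels do not say whether the arrays hold all of the eluted RNA or a part of it, nor which arrays RMA was run on together. A change in transcript amount and a change in tail-dependent recovery therefore give the same kind of difference, and unfractionated RNA was not analysed here. The median log2 RMA values of the arrays were 8.41 and 8.48 in the Gld2 shRNA cultures and 8.41 and 8.43 in the scrambled shRNA cultures. Across all 28826 probe sets, Pearson's r was 0.996 between the Gld2 shRNA cultures and 0.997 between the scrambled shRNA cultures, against 0.989 to 0.993 between cultures of different groups. The median absolute log2 difference was 0.106 between the Gld2 shRNA cultures and 0.075 between the scrambled shRNA cultures. Against the scrambled shRNA cultures it was 0.109 and 0.105 for Gld2 shRNA replicate 1, and 0.172 and 0.158 for Gld2 shRNA replicate 2. By this measure replicate 1 was about as near the controls as replicate 2, while replicate 2 lay farther from the controls. The number of arrays limits the precision. The labels do not say whether the cultures of a group came from separate preparations, so p-values measure the spread between these cultures, which may be partly technical.

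The transcript of the targeted gene was reduced. Tent2 (probe set 10820478) stood at 9.50 and 9.35 in the Gld2 shRNA cultures and at 10.73 and 10.67 in the scrambled shRNA cultures. The means were 9.42 ± 0.106 (SD, n = 2) and 10.70 ± 0.0428 (SD, n = 2), a log2 difference of -1.28 with a standard error of 0.0751 and a 95% confidence interval from -1.47 to -1.10. Tent2 was 2.43-fold lower in the Gld2 shRNA cultures, with an adjusted p of 0.000754 by limma with Benjamini-Hochberg adjustment over the genes tested. Both knockdown cultures lay below both controls, in the direction that the labels give.

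Knockdown of Gld2 went with a large rise of genes of the antiviral interferon response and with many smaller falls, among them Grin2a and several ion channel and sterol synthesis genes. Of 14497 genes, 594 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 245 higher and 349 lower in the Gld2 shRNA cultures. The rises were the larger changes, with 74 genes at least 2-fold higher and 3 at least 2-fold lower. The 3 genes with at least 2-fold falls were Slc36a1, Tent2 and Stc1. The median log2 difference over all genes was -0.02. By unadjusted p under 0.05 with at least 1.5-fold, a descriptive count, 136 genes were higher and 75 lower, 211 in all, against 0 and 2 in the other 2 ways of splitting the 4 arrays into pairs. Each of those splits puts 1 culture of each treatment on both sides, so the treatment difference widens their spread. Few calls are thus built in, and the 0 and 2 are no chance level for the 211. The numbers of genes past the adjusted threshold varied with the culture left out, in fits that take the spread from the other group alone. Both fits without a Gld2 shRNA culture use the same spread, that of the scrambled shRNA cultures, so spread does not explain the gap between them. Gld2 shRNA replicate 2 lay farther from the controls than replicate 1, so many calls, most of all falls, depended on it. Higher genes numbered 1283 and 172 without Gld2 shRNA replicate 1 or 2, and 82 and 85 without scrambled shRNA replicate 1 or 2, while lower genes numbered 1406, 99, 3 and 7 in the same order. Centring each array on its median gave 558 higher and 1367 lower genes, and removing the trend of the values with gene length, a step added after the data were seen, gave 266 higher and 250 lower.

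**Figure D1:**
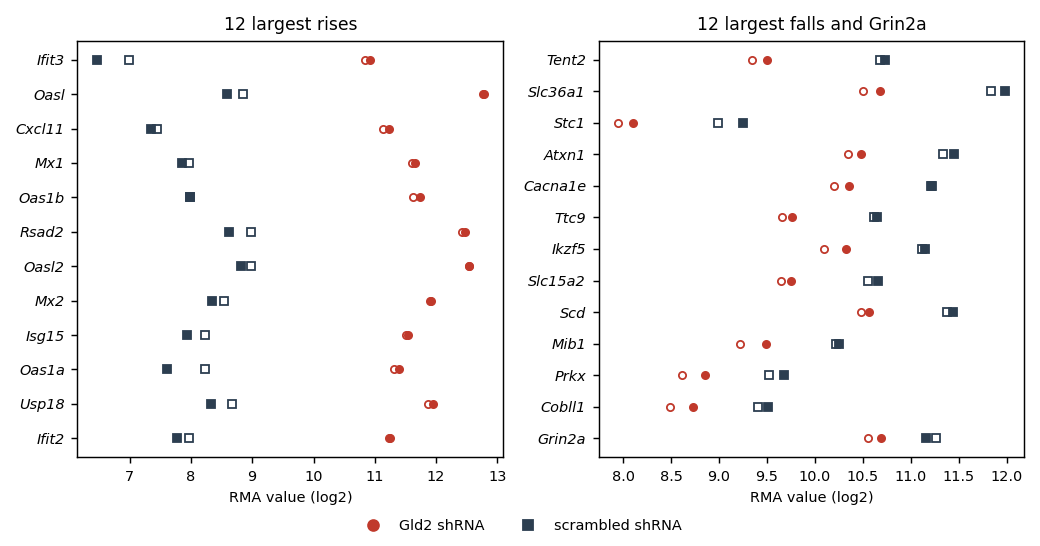
Log2 RMA values in each culture for the 12 largest rises (left) and for the 12 largest falls with Grin2a (right). Circles are Gld2 shRNA cultures and squares scrambled shRNA cultures, filled for replicate 1 and open for replicate 2. For every gene shown both cultures of a group lie on the same side of the other group, with Ifit3 at 10.93 and 10.85 against 6.47 and 6.99.

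The 12 largest rises were between 10.3-fold and 17.8-fold. Ifit3, an interferon-induced antiviral gene, was 17.8-fold higher (log2 difference 4.16, standard error 0.165, adjusted p = 0.000159 by limma with Benjamini-Hochberg adjustment). Oasl, of the family of 2′-5′ oligoadenylate synthetases and related proteins, rose 16.6-fold, and the interferon-induced chemokine Cxcl11 rose 13.9-fold. Mx1 and Mx2, which encode GTPases with antiviral activity, rose 13.1-fold and 11.1-fold. Oas1b, Rsad2, Oasl2, Isg15, Oas1a, Usp18 and Ifit2 made up the rest, and 11 of the 12 belonged to the interferon and innate immune list fixed before the data were examined, Cxcl11 being the exception. Each of the 12 stayed past the threshold without any single culture. Members of the Oas, Ifit and Mx families are similar in sequence, so probe sets of one may take up signal from another.

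Of 34 measured members of the interferon and innate immune list, 31 rose, 0 fell and 3 did not pass the test. Adjusted over the list alone, 32 rose. The members with the smallest p were Oas1b (3.69), Mx1 (3.71), Oasl2 (3.64) and Oasl (4.05), given as log2 differences. The transcription factors of the pathway also rose, Irf7 by 2.80, Stat2 by 1.43 and Irf9 by 1.40. The 3 members that did not pass were Tlr3 (0.54, adjusted p = 0.0688), Oas3 (0.21, adjusted p = 0.239) and Ifit1 (0.15, adjusted p = 0.325), by limma with Benjamini-Hochberg adjustment. Ifit1 had means of only 5.63 and 5.48, in the lowest decile of mean level. The median of the list was 2.13, and camera set it apart from the other genes with an adjusted p of 5.23e-53 over 26 lists. The call was lost at an adjusted p = 0.443 with an estimated correlation, a setting with little power at 2 residual degrees of freedom, while fry gave an adjusted p of 0.0109. Microglia, which respond strongly to interferon, had a marker median of 0.15, described with the other cell types.

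**Figure D2:**
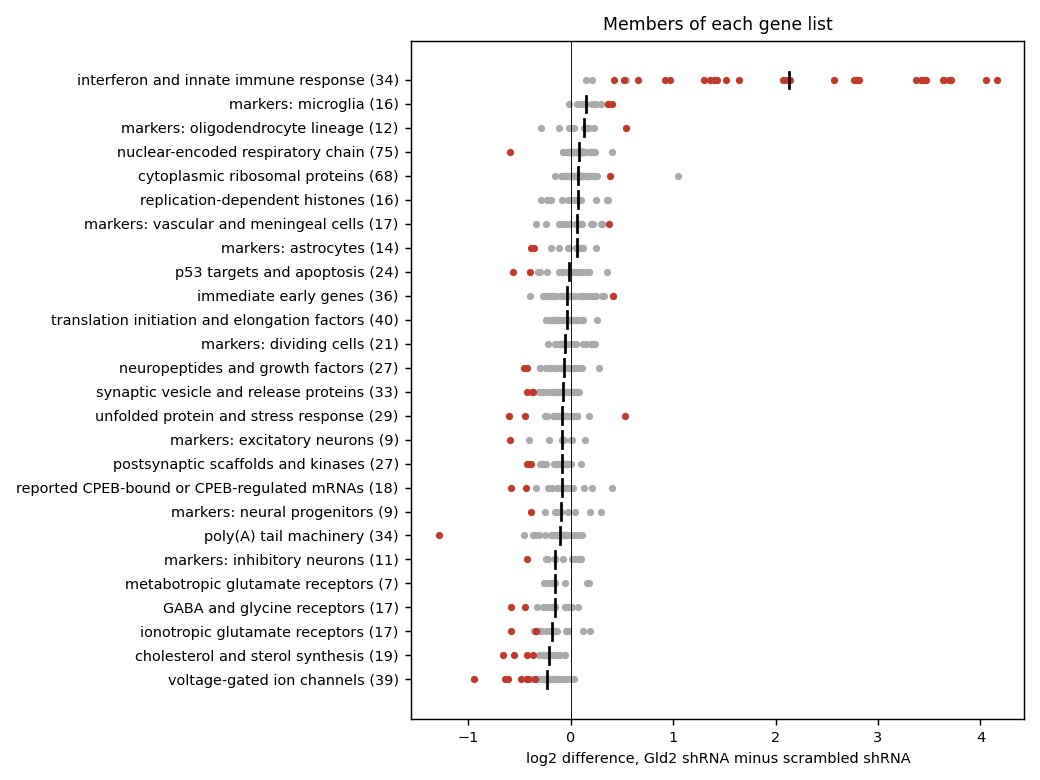
Log2 differences (Gld2 shRNA minus scrambled shRNA) of the measured members of the 26 gene lists, 1 dot per gene, with the number measured in brackets. Red dots passed an adjusted p under 0.05 and black bars are list medians, which run from 2.13 in the interferon list to -0.23 in the voltage-gated channel list.

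The largest falls were smaller than the rises, between 1.80-fold and 2.50-fold, and came from genes of varied function. Slc36a1, a proton-coupled amino acid transporter, was 2.50-fold lower (log2 difference -1.32, adjusted p = 0.00152 by limma with Benjamini-Hochberg adjustment), and Tent2 followed. Stc1, which encodes the secreted glycoprotein stanniocalcin, was 2.13-fold lower, Atxn1 (ataxin 1) 1.97-fold lower and Cacna1e, a pore subunit of R-type calcium channels, 1.92-fold lower. Ttc9, Ikzf5, the peptide transporter Slc15a2, the fatty acid desaturase Scd, the ubiquitin ligase Mib1, the kinase Prkx and Cobll1 made up the rest, with log2 differences from -0.92 to -0.85. Some of these calls were lost when a scrambled shRNA culture was left out, a fit whose spread comes from the Gld2 shRNA cultures alone. A lost call there need not mean that a fall rested on 1 control. Over the fits without 1 culture, Cacna1e ran from -1.02 to -0.86 and Mib1 from -1.02 to -0.74. Without scrambled shRNA replicate 1 only Slc36a1, Tent2 and Ttc9 stayed past the threshold, and without scrambled shRNA replicate 2 Cacna1e, Ikzf5, Mib1, Prkx and Cobll1 lost it, with no change of sign.

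Grin2a, which encodes the GluN2A subunit of the NMDA receptor and whose mRNA has been reported as a target of cytoplasmic polyadenylation in neurons, fell. Grin2a (probe set 10731539) had means of 10.62 ± 0.0912 (SD, n = 2) and 11.21 ± 0.0720 (SD, n = 2) in the Gld2 shRNA and scrambled shRNA cultures. It stood at 66.6% of the control level, with a log2 difference of -0.59, a standard error of 0.0756 and a 95% confidence interval from -0.77 to -0.40 (adjusted p = 0.0181, limma with Benjamini-Hochberg adjustment). The call was lost without scrambled shRNA replicate 1 (adjusted p = 0.147), without scrambled shRNA replicate 2 (0.186), when unnamed probe sets were tested along with the genes (0.0549) and without moderation across genes (0.278), all fitted in limma with Benjamini-Hochberg adjustment. Over the alternatives its adjusted p ran from 2.60e-06 to 0.278 in limma. Of 18 measured mRNAs reported as bound or regulated by the tail-controlling protein CPEB, 2 fell, Grin2a and the inositol trisphosphate receptor Itpr1 (-0.44), 0 rose and 16 did not pass. Adjusted over the list alone, 3 fell and 0 rose. Myc had a log2 difference of -0.34 and Ccnb1 of -0.22, neither past the threshold, and Camk2a, Map2 and Bdnf were at -0.08, -0.09 and -0.09. In this list 4 members had values above 0, the highest being Mos (0.40) and Egfr (0.21), which did not pass either. The median of the list was -0.09, and camera did not call it (adjusted p = 0.0914 over the 26 lists), although it did with a prior variance that follows the level (adjusted p = 0.0445, of a range from 0.0445 to 0.541 over the alternatives, the highest with an estimated correlation).

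Among the poly(A) tail machinery itself, the targeted gene was the only one of 34 measured members past the threshold over all genes, with 0 rising and 33 not passing. Adjusted over the list alone, 5 fell. Besides Tent2, the members with the smallest p were Cpeb4 (-0.31), Cnot6l (-0.45) and Cpeb1 (-0.37), a deadenylase subunit and CPEB proteins that did not pass over all genes. The list median was -0.10 and camera gave an adjusted p of 0.00169. That test includes Tent2, the target of the shRNA, so part of the shift restates the knockdown, and no test without Tent2 is given here. The call was lost at an adjusted p = 0.604 with an estimated correlation, with cyclic loess, and when genes under the median level were left out.

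Voltage-gated ion channel genes were lower in the Gld2 shRNA cultures. Of 39 measured members, 8 fell, 0 rose and 31 did not pass, and 24 fell when adjusted over the list alone. The calcium channel genes Cacna1e (-0.94) and Cacna2d1 (-0.61) and the potassium channel genes Kcna3 (-0.64) and Kcnq3 (-0.49) had the smallest p. In the list 38 members had values below 0. The median was -0.23, with an adjusted p of 1.80e-10 by camera. The call was lost at an adjusted p = 0.541 with an estimated correlation. Without Gld2 shRNA replicate 1 or 2 the fallen members numbered 20 and 4, and without either scrambled shRNA culture 0. Splitting the arrays by the final digit of their titles, which puts 1 culture of each treatment on each side, let camera call 4 lists, the channel, poly(A) machinery, postsynaptic and immediate early lists (smallest adjusted p = 0.000148), against 11 in the real split and 0 in the third. The third split mixes the treatments too, which widens its spread, so its 0 is no chance level for the 11. The 4 calls by final digit show that camera with the preset correlation can call such lists without a treatment difference between the sides.

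Receptor and synaptic lists also lay below 0, each with few members past the threshold. Of 17 ionotropic glutamate receptor genes, 3 fell, Grin2a, Grin3a (-0.34) and Gria3 (-0.33), 0 rose and 14 did not pass, and 8 fell when adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.000547, and adjusted p = 0.541 with an estimated correlation). Of 17 GABA and glycine receptor genes, the subunit genes Gabrg3 (-0.58) and Gabrb2 (-0.45) fell, 0 rose and 15 did not pass, with 3 falling when adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.00447, and adjusted p = 0.541 with an estimated correlation). Of 27 genes of postsynaptic scaffolds and kinases, Shank2 (-0.39), Nlgn1 (-0.43) and Dlg1 (-0.41) fell, 0 rose and 24 did not pass, with 4 falling when adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.00209, and adjusted p = 0.541 with an estimated correlation). Of 33 synaptic vesicle and release genes, the active zone genes Rims1 (-0.37), Pclo (-0.42) and Rims2 (-0.37) fell, 0 rose and 30 did not pass, with 5 falling when adjusted over the list alone. Their median was -0.07 (camera adjusted p = 0.0116, and adjusted p = 0.541 with an estimated correlation). Calls in these lists were lost without either scrambled shRNA culture, and most were also lost without Gld2 shRNA replicate 2. Over the fits without 1 culture the differences of the named genes kept their sign. Shank2 ran from -0.43 to -0.35, Nlgn1 from -0.51 to -0.35 and Dlg1 from -0.47 to -0.35. Rims1 ran from -0.37 to -0.36, Pclo from -0.48 to -0.36 and Rims2 from -0.42 to -0.33.

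The differences varied with gene length and signal level over the whole array, and more so in Gld2 shRNA replicate 2 than in Gld2 shRNA replicate 1. Against the control mean, decile 3 of level had medians of 0.17 in replicate 2 and 0.02 in replicate 1, and decile 6 had -0.13 and -0.07. The shortest genes were at 0.10 and -0.01 in the same order, and the longest at -0.16 and -0.10. The medians below pool both cultures. Among the longest genes (the top decile by genomic length) 122 were lower and 3 higher, with a median of -0.12, whereas in the bottom decile 4 were lower and 17 higher, with a median of 0.04. Channel genes were long, with a median genomic length of 131300 bp against 18043 bp over all genes. With the length trend removed, camera no longer called the ionotropic glutamate receptor, GABA and glycine receptor, postsynaptic, vesicle and ribosomal protein lists, while the channel list was still called at a median of -0.12 and the unfolded protein and stress response list became called (adjusted p = 0.0220). In that setting both calls were lost, each at an adjusted p = 0.743 with an estimated correlation. With genes under the median level left out, the GABA and glycine receptor, postsynaptic and vesicle lists lost their calls and the microglia list had too few members to be tested, and the vesicle list lost it with genes under the 25th percentile left out, without Gld2 shRNA replicate 2 or without scrambled shRNA replicate 1.

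**Figure D3:**
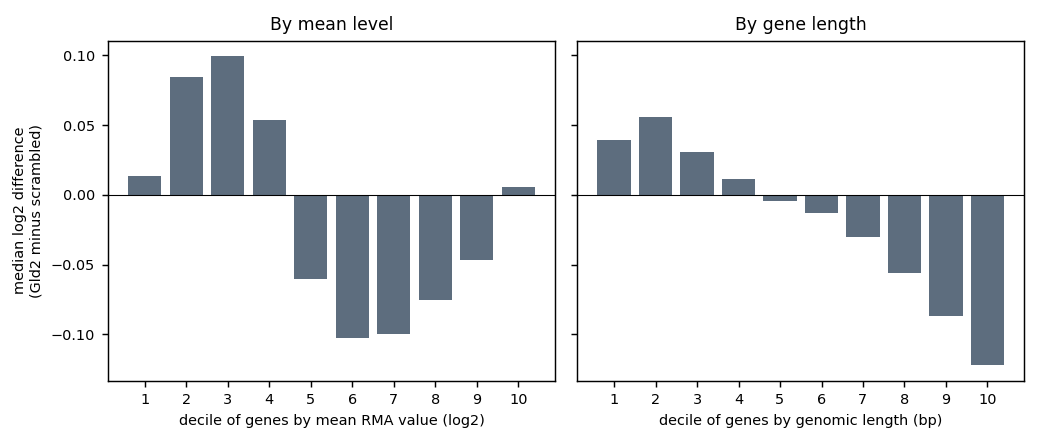
Median log2 difference (Gld2 shRNA minus scrambled shRNA) of genes grouped in deciles by mean log2 RMA value (left) and by genomic length in bp (right). The bars for gene length go from 0.04 for the shortest genes to -0.12 for the longest.

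Genes of cholesterol and sterol synthesis were lower as a group. Of 19 measured members, 4 fell, 0 rose and 15 did not pass, and 11 fell when adjusted over the list alone. Hsd17b7 (-0.66), Idi1 (-0.42) and Ebp (-0.37), enzymes of the pathway, and the cholesterol transfer protein gene Stard4 (-0.55) were those that fell. All 19 values were below 0, with a median of -0.21 and an adjusted p of 5.76e-07 by camera. The call was lost at an adjusted p = 0.443 with an estimated correlation, while fry gave an adjusted p of 0.0109. Without scrambled shRNA replicate 1 or scrambled shRNA replicate 2 the fallen members numbered 0.

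The respiratory chain and ribosomal protein lists had medians slightly above 0, with almost no member past the threshold. Of 75 nuclear-encoded respiratory chain genes, Ndufa10 fell (-0.59), against the direction of the list, 0 rose and 74 did not pass. Adjusted over the list alone, 0 rose and 0 fell, and the median was 0.08 (camera adjusted p = 7.84e-05, and adjusted p = 0.541 with an estimated correlation). Of 68 cytoplasmic ribosomal protein genes, Rps21 rose (0.38), 0 fell and 67 did not pass. The Rps21 call rested on 1 of its 4 probe sets, the other values being 0.13, 0.08 and -0.0127, and with the mean of a gene's probe sets 0 ribosomal genes rose. Adjusted over the list alone, 0 rose and 0 fell, and the median was 0.07 (camera adjusted p = 9.56e-05, and adjusted p = 0.541 with an estimated correlation). By limma, 3687 of all genes were at an unadjusted p under 0.05.

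Cell type markers moved far less than the interferon genes. Of 16 microglia markers, Ctss (0.37) and Fcer1g (0.41) rose, 0 fell and 14 did not pass, with 5 rising when adjusted over the list alone. Their median was 0.15 (camera adjusted p = 5.05e-05, and adjusted p = 0.541 with an estimated correlation). Neither marker passed without Gld2 shRNA replicate 2 or without either scrambled shRNA culture. Of 14 astrocyte markers, Gja1 (-0.39) and Slc4a4 (-0.35) fell, 0 rose and 12 did not pass, with a median of 0.06 and, adjusted over the list alone, 1 higher and 2 lower. Of 12 oligodendrocyte lineage markers, Cnp (0.54) rose, 0 fell and 11 did not pass, with a median of 0.13 and, adjusted over the list alone, 1 higher and 1 lower. Of 17 vascular and meningeal markers, Tagln (0.37) rose, 0 fell and 16 did not pass, with a median of 0.06 and, adjusted over the list alone, 1 higher and 1 lower. Of 9 excitatory neuron markers, the dentate granule cell gene Prox1 (-0.59) fell, 0 rose and 8 did not pass, with a median of -0.08 and, adjusted over the list alone, 3 lower. Of 11 inhibitory neuron markers, the neuropeptide gene Vip (-0.43) fell, 0 rose and 10 did not pass, with a median of -0.15 and, adjusted over the list alone, 3 lower. Of 9 neural progenitor markers, Dcx (-0.38) fell, 0 rose and 8 did not pass, with a median of -0.09 and, adjusted over the list alone, 2 higher and 2 lower. None of 21 markers of dividing cells passed over all genes or adjusted over the list alone, and their median was -0.05. Of these marker sets camera called only the microglia set, and the adjusted p of the others ran from 0.0841 to 0.926. With genes under the 25th percentile of level left out, the oligodendrocyte set was called too (adjusted p = 0.0371, of a range from 0.0371 to 0.541 over the alternatives).

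The remaining lists were not called by camera, with adjusted p from 0.0914 to 0.932. Of these, camera called the unfolded protein and stress response list with the length trend removed (adjusted p = 0.0220, of a range from 0.0220 to 0.680, and adjusted p = 0.743 with an estimated correlation) and the neuropeptide list without Gld2 shRNA replicate 1 (adjusted p = 0.0451, of a range from 0.0451 to 0.708). In the unfolded protein and stress response list, 29 members were measured, Hmox1 (-0.60) and Trib3 (-0.45) fell, the small heat shock protein gene Hspb1 (0.53) rose and 26 did not pass, with a median of -0.08 and, adjusted over the list alone, 1 higher and 3 lower. Of 27 neuropeptide and growth factor genes, Igf1 (-0.45) and Vip fell, 0 rose and 25 did not pass, with a median of -0.06 and, adjusted over the list alone, 6 lower. Of 24 p53 target and apoptosis genes, Gadd45a (-0.56) and Tp53inp1 (-0.40) fell, 0 rose and 22 did not pass, with a median of -0.02 and, adjusted over the list alone, 1 higher and 4 lower. Of 36 immediate early genes, Gadd45b (0.41) rose, 0 fell and 35 did not pass, with a median of -0.04 and, adjusted over the list alone, 2 higher and 1 lower. No member passed over all genes among 16 replication-dependent histone genes (median 0.07), 40 translation factor genes (median -0.04) and 7 metabotropic glutamate receptor genes (median -0.15). In these 3 lists the members with the smallest p were H2ac4 (0.37), Eif4g3 (-0.20) and Grm4 (-0.26). Adjusted over the list alone, 0 members of these 3 lists passed. Outside the interferon list, Tent2 was the only list member past the threshold without scrambled shRNA replicate 1 or without scrambled shRNA replicate 2. The directions of the p53, immediate early and metabotropic receptor medians turned under cyclic loess or with the length trend removed.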

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

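The counts and identifiers in this part were examined after the main results were seen. Probe sets outside the genes tested also differed between the groups, a signal in data the comparisons above do not use. When all 28826 probe sets were tested together with limma and Benjamini-Hochberg adjustment, 57 without a gene name were higher and 63 lower in the Gld2 shRNA cultures, 0.902% of 13311. Of those with several gene names, 5 were higher and 0 lower. The most changed unnamed probe set, 10801975, was 35.4-fold higher (log2 difference 5.15, standard error 0.175, adjusted p = 0.000671 by limma with Benjamini-Hochberg adjustment), and 10801973 was 12.1-fold higher. The control mean of 10801975 was 5.38, in the lowest decile of level and not shown to be above background, so its fold is uncertain. Probe sets 10886864 and 10794544 had the largest falls among the unnamed, 2.33-fold and 2.32-fold lower. The annotation used here pairs none of these 4 with a gene.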

How the results depend on the processing

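Removal of the gene length trend, alone or after cyclic loess, was chosen after the data were seen, and the other settings before. In the moderated fits Tent2 was lower and past the threshold (log2 -1.36 to -1.16), and the 12 largest rises stayed past it wherever tested. The 594 genes (245 higher, 349 lower) became 2232 (621, 1611) with a prior variance following the level, 1925 (558, 1367) with median centring, 1484 (467, 1017) at an adjusted p under 0.10 and 204 (133, 71) with at least 1.5-fold. Fewer genes or more probe sets tested gave 1596 in all and 1287 lower above the median level, 1297 and 949 above the 25th percentile, and 313 and 116 over all probe sets. Of these 313, only 177 were the probe sets that stand for the tested genes (127 higher, 50 lower, 71.8% higher against 41.2%). A linear model without moderation, whose test has only 2 degrees of freedom, called 1 gene higher (Tgm2) and 0 lower, with 2273 at an unadjusted p under 0.05, and 0 of the 12 largest rises, 0 of the 12 largest falls and neither Tent2 (adjusted p = 0.221) nor Grin2a (adjusted p = 0.278). Leaving out 1 culture gave 85 to 2689 genes, 82 to 1283 higher and 3 to 1406 lower. With cyclic loess the count was 668, with the mean of a gene's probe sets 606, with the length trend removed 516 and with both trends removed 584 (311 higher, 273 lower). The count by unadjusted p and fold, 211, became 563 over all probe sets and 198 to 293 without 1 culture. The 11 lists called became 6 of 22 tested above the median level, 7 with the length trend removed (6 kept, 1 gained), 5 with both trends removed, 0 with an estimated correlation, 2 with fry and 10 to 12 without 1 culture. The interferon, channel, sterol, microglia and respiratory chain lists were the 5. The cyclic loess setting, which removes differences tied to the level, also ended the call of the poly(A) machinery list. Reversals concerned genes and lists that were not past the threshold, with values as far from 0 as -0.15 (metabotropic receptor list) and -0.14 (Gria1). With cyclic loess App turned to -0.0174, Vegfa to 0.0262, the immediate early list to 0.0344 and the p53 list to 0.0502. With the length trend removed Gria1 turned to 0.0106, Map2 to 0.0488 and the metabotropic receptor list to 0.0347. With both removed Bdnf turned to 0.0319, Map2 to 0.0131, Vegfa to 0.0148, the immediate early list to 0.00987, the p53 list to 0.0354 and the metabotropic list to 0.0125. Without 1 culture Arc ran from -0.264 to 0.0898 and the immediate early list from -0.151 to 0.0488, both highest without Gld2 shRNA replicate 2. Apart from tests on fewer genes or arrays, the cause was not tested. The final digits of the titles may only number the samples. The deviations of same-numbered cultures from their group means correlated at 0.143 across genes. With 2 cultures per group both pairs give this same value by construction, so it is 1 check. A replicate block gave 565 genes (233 higher, 332 lower), 487 of them shared with the 594, and changed 0 list calls. Without detection calls, the share of dim genes under background stayed unknown.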

Other observations

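All gene groups in the first paragraphs of this part were chosen after the gene values were seen, as were the comparisons with microglia, neuron markers and the construct and those with both trends removed. The Fisher and camera p-values of these gene groups do not allow for that choice. They describe the groups and are not support for a shift. The other tests on the 3 patterns were written before their results were seen. Further immune genes rose with the interferon list. Of 33 chemokine ligands, 14 rose and 0 fell, against 0.558 rises expected for a random group of that size (Fisher's exact test, adjusted p = 4.61e-16 over 14 tests). That test takes genes as independent, and camera lost the call at an adjusted p = 0.0937 with an estimated correlation. Ccl12 (log2 difference 2.54), Ccl7 (2.44) and Cxcl1 (1.77) were among them, and 2 of the 33 also belong to the interferon list. Of 37 genes of MHC class I and antigen presentation, 21 rose and 0 fell (adjusted p = 3.64e-27, and by camera adjusted p = 0.0937 with an estimated correlation), among them RT1-S3 (2.14), Tapbp (1.03) and B2m (0.43), with 3 shared with the interferon list. RT1 genes are close paralogs and may share probe signal, so the count of 21 may exceed the number of separate loci that rose, which was not tested. Of 22 complement genes, C3 (1.60), C1s (1.32), C1r (1.26) and Serping1 (1.39) rose and Cd55 (-0.44) fell (adjusted p = 0.00134 for the rises, and by camera adjusted p = 0.130 with an estimated correlation). The cytokine genes Tnf (1.34) and Il6 (0.93) and the iron-binding protein gene Lcn2 (1.91) rose, whereas Ifnb1, the interferon beta gene, had a log2 difference of 0.30 that did not pass (adjusted p = 0.159 by limma with Benjamini-Hochberg adjustment).

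Some members of 3 further groups fell, and none of these groups was called with an estimated correlation. Of 29 antioxidant genes reported as NRF2 targets, Hmox1 (-0.60), Nqo1 (-0.54), Nfe2l2 (-0.43), which encodes NRF2 itself, and Srxn1 (-0.36) fell and 0 rose (Fisher's exact test, adjusted p = 0.0114, and by camera adjusted p = 0.313 with an estimated correlation). Camera with its preset correlation also lost this group without Gld2 shRNA replicate 2 (adjusted p = 0.0564, of a range from 0.0215 to 0.0564 over the settings). Of 16 circadian clock genes, Cry1 (-0.40), Bhlhe41 (-0.52), Clock (-0.44) and Per3 (-0.48) fell and 0 rose (adjusted p = 0.00134, and by camera adjusted p = 0.313 with an estimated correlation of 0.374). The potassium channel group shares members with the voltage-gated channel list, so its test partly recounts falls already seen there. Of 83 potassium channel genes 10 fell and 0 rose (Fisher's exact test, adjusted p = 0.000137, and by camera adjusted p = 0.130 with an estimated correlation). With the length trend removed 8 fell, the median was -0.0231 and camera no longer called the group (adjusted p = 0.0932, of a range from 0.00260 to 0.0932 over the settings). Of 309 solute carrier genes 11 fell and 2 rose, which was not past the threshold (adjusted p = 0.255). Without scrambled shRNA replicate 1 or scrambled shRNA replicate 2, 0 genes of the antioxidant, clock and potassium channel groups passed (without Gld2 shRNA replicate 2, 1, 0 and 3), against 10 chemokine, 6 antigen presentation and 4 complement genes.

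The rise of interferon response genes was set against 3 explanations. More microglia in the Gld2 shRNA cultures would raise their markers by about as much. These had a median of 0.15, with a 95% bootstrap interval over markers from 0.12 to 0.25 against 1.44 to 2.81 for the interferon list. The gap argues against more microglia as far as the markers lay above background, which was not tested. Only 8 of the 16 markers lay at or above the 25th percentile of level, and the intervals hold no spread between cultures. A trend with signal level is argued against by its size, since the medians of the level deciles ran only from -0.10 to 0.10, against 2.13 for the list. The list's median of 2.17 with cyclic loess could therefore hardly have come out otherwise and adds little. A response to the shRNA construct or its delivery, not to less Gld2, stays open, because the labels name 1 Gld2 shRNA treatment and no rescue, and less Gld2 may equally be the source.

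The fall of the voltage-gated ion channel list, with a median of -0.23, was weighed against trends and cell makeup. The list stayed called at -0.16 with cyclic loess and at -0.12 with the length trend removed (95% bootstrap interval -0.14 to -0.08). Both camera calls were lost with an estimated correlation (adjusted p = 0.448 and adjusted p = 0.743). Part of the fall remained with either trend removed, and the intervals stayed below 0. These intervals resample members as if independent and hold no spread between cultures, while the members' estimated correlation was 0.406 in the main fit. They cannot decide whether either trend was the whole cause, and the length trend may account for much of the fall. With both removed the median was -0.0926, short of the -0.1 set for the test, so both trends together stay open. Fewer neurons also stay open, since neuron markers had a median of -0.0863, above that of the channels (permutation p = 0.00248), but with the length trend removed both medians were -0.12 (permutation p = 0.983).

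The fall of the sterol synthesis list, with a median of -0.21, kept its size. The median was -0.19 with cyclic loess, -0.21 with the length trend removed and -0.19 with both removed, and the list was called in each, though not with an estimated correlation (adjusted p = 0.428, 0.493 and 0.283). The median genomic length of the list was 15342 bp, near the 18043 bp over all genes. Removing the length trend could thus hardly have changed the list's median, so that setting adds little. That the median hardly changed with cyclic loess argues against a trend with level as its cause in these arrays. The 95% bootstrap intervals of the medians in these settings ended at -0.13, -0.15 and -0.14, but they resample members and hold no spread between cultures. A response of sterol genes to less Gld2, or to the construct, may be considered as a hypothesis, and no other explanation was tested. Its members passed the threshold in 0 cases without either scrambled shRNA culture.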
